A study of Arabidopsis thaliana with 3 samples.

How the data were processed

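Whole-genome bisulfite sequencing was done on genomic DNA of whole 12-day-old Arabidopsis thaliana seedlings grown at 22 °C with 16 h of light per day, per the labels. The samples were 1 Col-0 wild-type library and 1 library each of the knockout lines ros1-3 and ros1-4. ROS1 is a DNA glycosylase that removes 5-methylcytosine. Bisulfite turns unmethylated cytosine into uracil, so a cytosine still read as cytosine counts as methylated. Sequencing was contracted out with standard Illumina library construction, per the labels' protocols.

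The deposited files hold counts of methylated and unmethylated reads per cytosine and strand, per the file headers, with the sequence context (CG, CHG or CHH, where H is A, C or T). Trim Galore 0.2.8 and BWA are named, with the genome build TAIR10, per the submitters' processing notes. The software that counted the reads, its filters and any removal of duplicate reads are not given in the sources used here. The counts were used as deposited, without normalization. Every listed cytosine had at least 1 read. Positions in the files count from 0 and are given below counted from 1. The files analysed cover chromosomes 1 to 5, and the chloroplast was not analysed here. Entries whose 3-base sequence did not match the stated context were dropped (412 in wild type, 492 in ros1-3 and 313 in ros1-4). Positions listed more than once were dropped too (46, 94 and 76 entries).

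Methylation levels are methylated reads over all reads. Cytosines with at least 4 reads in each of the 3 libraries entered every comparison. The genome was split into 200-bp tiles, and a tile was tested in a context where it held at least 4 such cytosines. Each pair of libraries was compared by a two-sided Fisher's exact test on the summed reads, with Benjamini-Hochberg adjustment per context and comparison. A tile was called at an adjusted p below 0.01 and a difference of at least 40 points in CG, 20 in CHG or 10 in CHH. It counted as higher or lower when called in at least 1 context in that direction and in none in the other. Called tiles at most 200 bp apart were joined into regions. Because there was 1 library per genotype, a test on reads compares these libraries and not the genotypes, and no p-value across genes was computed. Intervals are 95% Wilson intervals, and Newcombe intervals for differences. A count of 0 is given with the level that 3 reads would give. Reads without molecular identifiers are not independent molecules, so tests, intervals and limits cover counting error only.

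The reads summed over cytosines came to 1007547295 in wild type, 571363089 in ros1-3 and 760996496 in ros1-4. In tested tiles the median number of CG reads was 259, 158 and 209 respectively. On simulated tiles with the real read numbers, 100% of 200 tiles raised by 60 points in CG were called in each line. For tiles raised by 30 points in CHG the shares were 96% in ros1-3 and 99.5% in ros1-4. For tiles raised by 15 points in CHH they were 96.5% and 96%, and 0 unchanged tiles were called. Raised tiles were drawn from tiles with a pooled level below 30%. The simulated reads held counting error only, so the 0 gives no rate of false calls between real libraries.

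Gene names, and which tiles and cytosines lie in or beside a gene, come from the RefSeq gene table of assembly TAIR10.1. Its gene coordinates are not printed, since the build of the files is TAIR10. As a check, the complement of a start codon lay exactly at a gene's end for 7.73% of 54888 gene ends, against 1.94% or less when shifted by 1 to 3 bp. The table gives no strand, so both 1000-bp flanks of a gene were tested in place of the planned promoter. A gene counted in both lines where the same part was called in both. Left and right flanks lie at the lower and higher coordinate. The table has no class for transposable element genes, and pseudogenes were used in their place. All 112 genes of 10 lists matched the table. The lists cover DNA demethylases, demethylation cofactors and repair, methyltransferases, RNA-directed DNA methylation, ROS1 targets known from other work, imprinted or silenced genes, immune receptors, stomatal lineage, abscisic acid and seed dormancy, and housekeeping.

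The lists, comparisons, tests, thresholds and the rule for naming genes were fixed before the data were examined. The rule names up to 4 called members per list by size of difference, and always ROS1, DME, DML2, DML3, EPF2, DOGL4, NIC3, RMG1 and RLP43. It also names the 12 higher and 6 lower regions with the most calls shared by both lines, and the 5 regions with the most calls in each line alone, over tiles that also differed directly from the other line. Enrichment of tiles was set against 1000 circular shifts of the calls along each chromosome. Sharing between lines was set against 20 simulations without any difference, and against a random split of the wild-type reads into 2 parts.

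Alternatives planned were minimums of 1 and 10 reads, 100-bp tiles, differences of 50, 30 and 20 points, an adjusted p of 0.001 and equal depth at each cytosine. Others were counting each cytosine once, other flank lengths, the gene body, and counting adjacent tiles as shared. Alternatives added after seeing the data were a correction for non-conversion, leaving out chromosome 2 from 9 to 16 Mb, removing an estimated share of reads of the other ros1 library, and applying the minimums of 1 and 10 reads to named genes and regions. The planned correction with chloroplast reads was not run; the CHH level in 5 housekeeping gene bodies stood in for it. That correction first used the level of each context and was changed to the CHH level after its result was seen, because CG in gene bodies is methylated in wild type. Computations used Python 3.11.15, NumPy 2.4.6, Numba 0.67.0 and PyArrow 21.0.0. SciPy 1.17.1 served to check the test, and matplotlib 3.10.9 drew the figures.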

Results

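DNA methylation was measured at single cytosines in seedlings of the wild type and of the knockout lines ros1-3 and ros1-4, with 1 library per genotype. No replicate check exists for any difference given here. Wild type had a mean of 25.4 reads per covered cytosine, ros1-3 had 15.3 and ros1-4 had 19.6. At least 4 reads covered 97.6% of CG sites in wild type, 85.4% in ros1-3 and 92.9% in ros1-4. For CHH sites the shares were 95.3%, 72.8% and 84.6%. The ros1 libraries were thinner over AT-rich DNA. In tiles of 20 to 25% GC ros1-3 had 6.39 reads per cytosine and wild type 19.6, and in tiles of 45 to 50% GC the means were 18.97 and 24.4. Ros1-4 had 10.7 and 22.4 reads in the same tiles.

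ROS1 (AT2G36490), the gene disrupted in both lines, had reads over its body in each library, but some body tiles lacked many cytosines in ros1-3. At 15314001 to 15314200, 56 of 79 cytosines had no reads in ros1-3, against 1 in wild type and 1 in ros1-4. At 15314801 to 15315000 the counts were 17 of 58 in ros1-3, 0 in wild type and 2 in ros1-4. At 15313801 to 15314000 ros1-4 lacked more, with 18 against 3 in ros1-3. The counts hold no measure of the ROS1 transcript, so they do not check the labels. Its body carried 0.707% CHG methylation in wild type (95% interval 0.580 to 0.861), 7.18% in ros1-3 (6.69 to 7.71) and 5.00% in ros1-4 (4.63 to 5.40). These gains stayed below the 20-point threshold over the whole body. They were concentrated near 1 end of the gene, in tiles of chromosome 2 between 15308401 and 15309400. In the tile at 15308401 to 15308600 CHG methylation was 3.14% in wild type, 54.1% in ros1-3 and 72.5% in ros1-4, and it was called in both lines. At the other end, the tile at 15314801 to 15315000 had 44.1% CG methylation in wild type, 96.4% in ros1-3 and 93.0% in ros1-4. CHH methylation there was 16.6%, 36.9% and 34.2%, and both contexts were called in both lines. The 1000 bp beyond the first end were nearly free of methylation in each library, with a CG level of 0 of 2390 reads in wild type, which allows up to 0.126%. The 1000 bp beyond the other end had 15.8% CG in wild type, 33.1% in ros1-3 and 31.7% in ros1-4, which was not called. ROS1 lies within a part of chromosome 2, from 9 to 16 Mb, which held 32.4% of the tiles that were called in ros1-3 and not in ros1-4 and also differed directly between the lines.

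**Figure D1:**
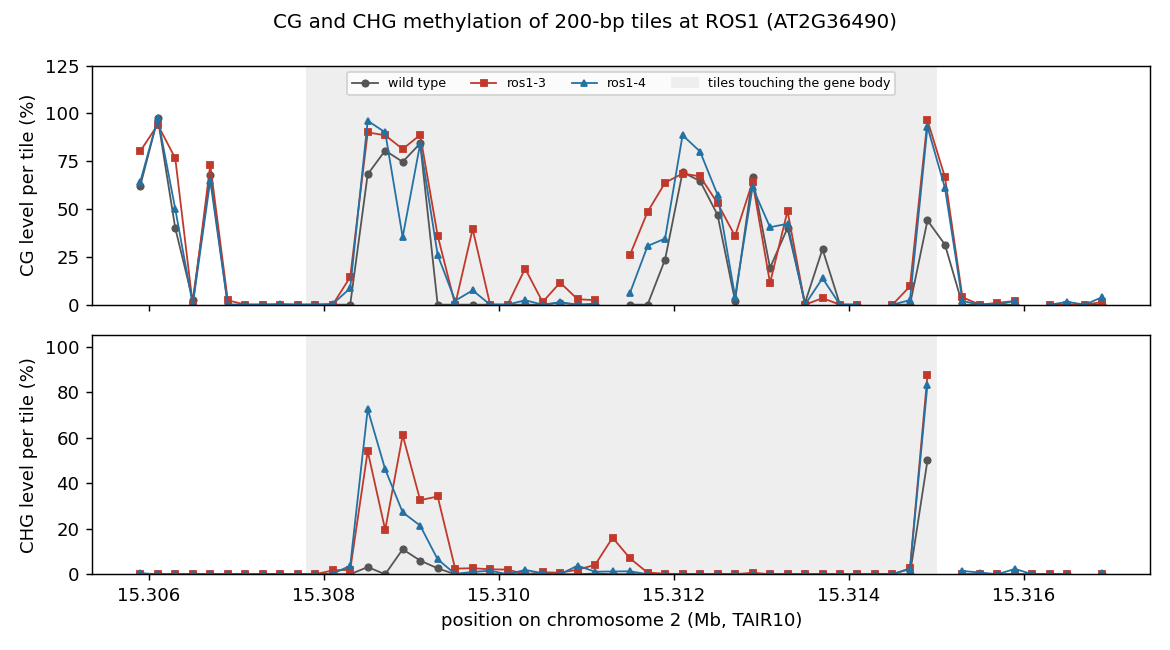
CG level (upper panel) and CHG level (lower panel) of 200-bp tiles, in percent, against position on chromosome 2 (Mb, TAIR10) at ROS1 in the 3 libraries. Points are tiles, gaps are tiles without enough covered cytosines, and the shaded tiles touch the gene body; CHG rises to 54.1% in ros1-3 and 72.5% in ros1-4 in the tile at 15308401 to 15308600, where wild type has 3.14%.

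Methylation over the whole genome was higher in both ros1 libraries than in wild type, in each context. The CG level was 24.0% in wild type, 28.2% in ros1-3 and 28.3% in ros1-4. The CHG level was 6.94%, 8.87% and 8.69%, and the CHH level 1.73%, 2.33% and 2.27%. In CG, ros1-3 lay 4.18 points above wild type (Newcombe 95% interval 4.17 to 4.19) and ros1-4 lay 4.34 points above it (4.33 to 4.35). In CHG the differences were 1.93 points (1.92 to 1.94) and 1.76 points (1.75 to 1.76). In CHH they were 0.602 points (0.5999 to 0.6037) and 0.542 points (0.540 to 0.544). When each cytosine counted once the CG differences were 2.001 and 1.98 points, the CHG differences 0.789 and 0.640 points, and the CHH differences 0.401 and 0.317 points. The bodies of 5 housekeeping genes had CHH levels of 0.0112% in wild type (0.00592 to 0.0214), 0.00924% in ros1-3 (0.00395 to 0.0216) and 0.0135% in ros1-4 (0.00713 to 0.0257), which did not differ within counting error.

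By reads, the differences were unevenly spread over the genome, but they were not confined to called tiles. Without the tiles called in either line, CG lay 3.53 points above wild type in ros1-3 and 3.59 points in ros1-4. In CHG these differences were 1.63 and 1.42 points, and in CHH 0.495 and 0.421 points. The levels of the classes below were computed by reads only. Over the whole genome, counting each cytosine once left 47.8% of the CG difference in ros1-3 and 45.6% in ros1-4. How far uneven depth contributes within each class was not tested. Tiles within 1000 bp of a protein-coding gene but outside gene bodies had a CG level of 18.3% in wild type, 27.3% in ros1-3 and 26.4% in ros1-4. Protein-coding gene bodies had CG levels of 15.6%, 17.0% and 17.5%. Tiles away from all these classes had CG levels of 44.2%, 57.3% and 54.6%. Pseudogenes, already methylated at 75.2% of CG reads in wild type, had 78.7% and 78.6%. In CHG the tiles beside genes had 8.38%, 13.8% and 12.97%, and gene bodies had 0.941%, 1.28% and 1.30%. In gene-body tiles of intermediate CG level (40 to 60%) with almost no CHG methylation and no call, the median difference from wild type was 2.31 points in ros1-3 and 2.40 points in ros1-4.

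**Figure D2:**
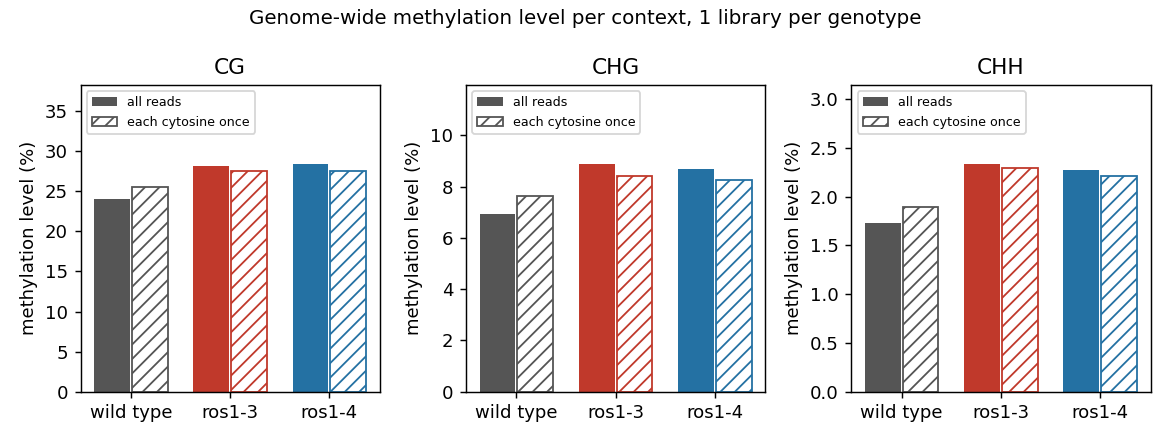
Methylation level in percent of all CG, CHG and CHH cytosines with at least 4 reads in each library, for the 3 libraries. Filled bars weight cytosines by reads and hatched bars count each cytosine once; by reads, CG is 24.0% in wild type, 28.2% in ros1-3 and 28.3% in ros1-4.

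The ros1-3 library gained methylation over wild type at far more places than it lost it. Of 561300 tiles tested, 12022 were higher in ros1-3 and 1448 were lower. By context, 6842 tiles were higher and 1081 lower in CG, 5228 and 75 in CHG, and 3646 and 339 in CHH. Tiles within 1000 bp of a protein-coding gene but outside bodies made up 38.3% of the higher tiles and 18.0% of those tested, and gene bodies 31.4% and 60.2%. The lower tiles lay mostly in gene bodies, at 72.5%. Among 27229 protein-coding genes with a tested flank, 1281 had a flank higher in ros1-3 and 12 a flank lower, while 106 had a body higher and 4 a body lower. EPF2 (AT1G34245), whose peptide restrains the formation of stomatal precursors, rose in its left flank from 5.55% CG in wild type (4.15 to 7.39) to 81.8% in ros1-3 (78.5 to 84.7), with a Benjamini-Hochberg adjusted p of 2.81e-199 by Fisher's exact test. CHG in that flank rose from 1.36% to 60.2% and CHH from 0.455% to 14.7%. The left flank of RMG1 (AT4G11170), a disease resistance gene, rose in CHH from 0 of 2030 wild-type reads, which allows up to 0.148%, to 11.1% in ros1-3 (9.21 to 13.2). Its CHG rose from 0 of 151 reads, which allows up to 1.99%, to 27.1%. In ros1-4 this flank of RMG1 had 7.92% CHH and 15.7% CHG, which were not called. The CHH call of RMG1 was lost at a minimum of 1 read, with a difference of 9.53 points. In the right flank of SUVH9 (AT4G13460), which helps recruit RNA polymerase V to methylated DNA, CG rose from 24.8% to 67.1% in ros1-3 and CHG in the left flank from 14.6% to 35.3%. Both levels also rose in ros1-4, but by less than the thresholds of 40 points in CG and 20 in CHG. They were therefore not called in ros1-4, and the direct comparison of the lines gave no call for them either. At a minimum of 10 reads the CG difference of SUVH9 in ros1-3 was 37.9 points and not called. With differences of 50, 30 or 20 points required, the tiles in ros1-3 came to 6503 higher and 482 lower, and with 100-bp tiles to 18079 and 3187.

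The ros1-4 library also gained methylation over wild type at more places than it lost it. Here 11580 tiles were higher and 1462 lower. By context, 7129 tiles were higher and 1068 lower in CG, 5037 and 96 in CHG, and 3069 and 362 in CHH. Tiles beside protein-coding genes made up 38.4% of the higher tiles and gene bodies 32.9%, and gene bodies held 69.4% of the lower tiles. A flank was higher in 1295 genes and lower in 17, and a body was higher in 107 and lower in 5. By Fisher's exact test EPF2 had a Benjamini-Hochberg adjusted p of 1.99e-224 and reached 81.3% CG (78.4 to 83.9) and 55.5% CHG (52.0 to 58.8) in its left flank. RD29A (AT5G52310), a gene induced by drought and abscisic acid, rose in the right flank from 2.17% CG in wild type (1.06 to 4.42) to 48.6% in ros1-4 (42.0 to 55.2). In ros1-3 the same flank had 34.6% (26.2 to 44.2), below the threshold of 40 points. NIC3 (AT5G23220), a nicotinamidase gene, rose in the right flank from 7.66% CHG (4.96 to 11.7) to 30.2% in ros1-4 (23.7 to 37.7) and had 24.0% in ros1-3. The left flank of NRPE1 (AT2G40030), the largest subunit of RNA polymerase V, rose in CHG from 9.28% to 30.7% in ros1-4, a call lost at minimums of 1 read (19.4 points) and 10 reads (9.93 points). In ros1-3 the CHG level of this flank was 16.0% and not called. With differences of 50, 30 or 20 points required, the tiles in ros1-4 came to 6483 higher and 459 lower, and with 100-bp tiles to 17677 and 3544.

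Tiles higher in both ros1 lines lay mainly outside gene bodies, and tiles lower in both lay mainly within them. In all, 7139 tiles were higher in both lines and 625 were lower in both. The higher tiles formed 5115 regions with a median length of 200 bp and a longest of 2200 bp. Tiles beside protein-coding genes made up 42.1% of the higher tiles, above the 20.1% that was the highest of 1000 shifts, and gene bodies 27.7%, below the lowest shift of 55.5%. Tiles in none of the classes made up 27.5% of the higher tiles and 14.3% of those tested, and pseudogenes 4.19% and 8.38%. Of the tiles lower in both lines, 73.4% lay in gene bodies, above the highest shift of 67.0%. Of the lower tiles 73.3% were called in CG alone in both lines, and of the higher tiles 33.7%. Flanks of 817 protein-coding genes were higher in both lines and those of 6 were lower, while bodies were higher in 63 and lower in 2. With flanks of 2000 bp the counts were 426 and 3, and with flanks of 500 bp 13 were lower.

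The calls overlapped more than independent lists of these sizes, which would share 248 higher and 3.77 lower tiles. The simulations without any difference shared 0 in each direction, but they held 0 calls in either line and so give no measure of sharing through the wild-type library. With the wild-type reads split so that each line had its own part, 6563 higher and 552 lower tiles were shared, but both parts come from 1 library. The covariance of the 2 lines' differences from wild type over tiles was 91.0 in CG against 2.81 simulated without effect, 20.7 against 2.03 in CHG and 2.86 against 0.354 in CHH. The simulated values hold counting error only. A deviation particular to the wild-type library would raise the covariance too, so this contrast does not separate it from changes shared by the lines. Of the higher tiles, 59.4% of those in ros1-3 and 61.6% of those in ros1-4 were shared, and of the lower tiles 43.2% and 42.8%. After an estimated share of reads of the other line was removed from each ros1 library, the shares were 43.7% and 50.2% of the higher tiles and 23.2% and 28.0% of the lower tiles. With differences of 50, 30 or 20 points, 3916 tiles were higher in both lines and 185 lower, and 1544 tiles of 100 bp were lower in both.

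Among the genes of the RNA-directed DNA methylation pathway, 3 of 17 had a higher flank in each line and 2 of them in both, with the same counts adjusted over the list alone. CLSY1 (AT3G42670), a chromatin remodeller that brings RNA polymerase IV to its targets, rose in the right flank from 0 of 272 CG reads in wild type, which allows up to 1.10%, to 53.9% in ros1-3 (46.9 to 60.8) and 64.1% in ros1-4 (57.5 to 70.1). Its CHH level there rose from 0.458% to 14.2% and 14.9%. DCL3 (AT3G43920), which cuts the small interfering RNAs of the pathway, rose in the left flank from 6.87% CHG (5.51 to 8.54) to 33.4% (29.2 to 37.9) and 33.3% (30.1 to 36.7). Of the 5 ROS1 targets known from other work, 3 had a higher flank in each line and 2, EPF2 and DOGL4, in both, again with the same counts adjusted over the list alone. DOGL4 (AT4G18650), a relative of the seed dormancy gene DOG1, rose in the right flank from 0.103% CG (0.0182 to 0.583) to 67.7% in ros1-3 (63.2 to 72.0) and 76.4% in ros1-4 (73.1 to 79.4), with Benjamini-Hochberg adjusted p of 5.78e-189 and 1.76e-278 by Fisher's exact test. The right flank of RLP43 (AT3G28890), a receptor-like protein gene, had 13.96% CG in wild type, 40.4% in ros1-3 and 36.5% in ros1-4, below the threshold.

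Other lists held few calls, each with the same count adjusted over the list alone. Of 12 imprinted or silenced genes, 1 had a higher flank and 1 a higher body in both lines. These were HDG8 (AT3G03260), where CHG in the right flank rose from 1.69% (0.575 to 4.84) to 54.8% in ros1-3 (42.5 to 66.6) and 28.2% in ros1-4 (19.8 to 38.6), and MPC (AT3G19350), whose body rose from 39.6% CHG to 72.5% and 75.4%. Of 17 immune receptor genes, 1 had a higher flank in both lines. This was RPP7 (AT1G58602), a resistance gene against downy mildew, with CHH in the right flank at 2.17% in wild type (1.41 to 3.33), 37.7% in ros1-3 (32.9 to 42.7) and 42.4% in ros1-4 (38.9 to 46.0). Of 14 stomatal lineage genes only EPF2 was called, in both lines. Of 16 genes of abscisic acid and seed dormancy, 0 were called in ros1-3 and 2, NIC3 and RD29A, in ros1-4. None of the 4 DNA demethylase genes, 12 cofactor and repair genes, 12 methyltransferase and maintenance genes or 5 housekeeping genes had a called flank or body in either line. For DME (AT5G04560), the demethylase of the central cell, body CG was 29.99% in wild type, 31.1% in ros1-3 and 31.4% in ros1-4. The left flank of DML2 (AT3G10010) had 0.432% CG in wild type, 6.12% in ros1-3 and 21.0% in ros1-4. The body of DML3 (AT4G34060) had CG levels of 0.0184%, 1.64% and 0.973%.

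Among regions higher in both lines, the 12 with the most shared calls lay above wild type in CG, CHG and CHH. They were chosen by these calls, so their rise follows from the choice. The first, 2200 bp at chromosome 3, 22746401 to 22748600, overlaps LHCA2 (AT3G61470), a light-harvesting protein gene of photosystem I, and rose from 35.6% CG in wild type to 86.3% in ros1-3 and 83.0% in ros1-4. Its CHG level rose from 10.8% to 49.7% and 42.4%. The region at chromosome 5, 19198001 to 19199400, overlaps AT5G47300 and rose from 5.00% CG to 71.2% and 72.3%. The region at chromosome 5, 15430201 to 15431800, overlaps AT5G38540 and rose from 0.373% CG to 75.6% and 83.0%. Chromosome 3, 15500401 to 15501400, lies 616 bp from AT3G43580 and rose from 8.69% CG to 92.1% and 91.9%, and from 0.4002% CHH to 13.7% and 14.3%. The region at chromosome 4, 8088201 to 8089400, overlaps AT4G13992 and rose from 6.10% CG to 72.3% and 78.8%. Further regions overlap MEE65 (AT2G01280) and AT1G62760 or lie beside AT5G22870 and AT4G01140, and the other 3 have no protein-coding gene within 1000 bp.

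Fewer regions were lower than wild type in both lines. Both comparisons used the same wild-type library, so a higher level particular to that library would look the same. At chromosome 5, 14089001 to 14090000, 574 bp from AT5G35940, CG fell from 75.5% in wild type to 15.5% in ros1-3 and 9.47% in ros1-4, and CHG from 30.9% to 0.878% and 0.488%. At chromosome 1, 7876801 to 7877800, overlapping AT1G22290, CHG fell from 41.6% to 1.38% and 3.46%. At chromosome 1, 13699201 to 13699600, 462 bp from SHM7 (AT1G36370), of the serine hydroxymethyltransferase family, CG fell from 76.0% to 7.80% and 2.06%. At chromosome 3, 16159401 to 16161200, overlapping AT3G44570 and AT3G44580, CG stayed at 91.6%, 91.5% and 91.1% while CHG fell from 69.6% to 49.9% and 48.0%. The remaining regions overlap AT5G11370 and EDA34 (AT4G00140).

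The 2 ros1 lines differed from each other in both directions, and tiles where ros1-3 differed from both other libraries were concentrated in a stretch of chromosome 2. Directly compared, 2697 tiles were higher in ros1-3 than in ros1-4 and 2053 were lower. Flanks of 134 genes were higher and of 106 lower. Between 9 and 16 Mb of chromosome 2, which holds 6.08% of the tested tiles, lay 32.4% of the tiles that were called in ros1-3 and not in ros1-4 and also differed directly between the lines. For the mirror kind in ros1-4 the share was 8.98%, and for tiles higher in both lines 6.61%. Where wild type had at most 2% CG and ros1-3 at least 60% in this stretch, ros1-4 had a median of 12.5% over 322 tiles. All 5 regions with the most calls in ros1-3 alone, counted over tiles that also differed from ros1-4, lay in this stretch. At chromosome 2, 10167401 to 10170200, 376 bp from AT2G23890, CG was 0.860% in wild type, 71.4% in ros1-3 and 13.2% in ros1-4. At 12104801 to 12106600, overlapping GATA13 (AT2G28340), of the GATA transcription factor family, the levels were 0 of 1865 reads, which allows up to 0.161%, 72.8% and 14.2%. At 13662201 to 13663800, overlapping AT2G32160, they were 0.0725%, 76.4% and 10.6%. The other 2 lie at 10547201 to 10549600 and 12348601 to 12350400 and have no protein-coding gene within 1000 bp.

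The regions with the most calls in ros1-4 alone, counted in the same way, were spread over chromosomes 1, 2, 3 and 4. At chromosome 1, 28515001 to 28516200, overlapping AT1G75945, CG was 91.7% in wild type, 77.9% in ros1-3 and 14.4% in ros1-4. At chromosome 3, 15776801 to 15777600, overlapping AT3G43970, it was 0 of 585 reads, which allows up to 0.513%, 18.8% and 87.0%. At chromosome 4, 10180601 to 10181000, 190 bp from AT4G18425, it was 0 of 785 reads, which allows up to 0.382%, 20.6% and 88.8%. CHH there was 0 of 2124 reads, which allows up to 0.141%, 3.90% and 24.3%. The other 2 have no protein-coding gene within 1000 bp. At chromosome 3, 8594801 to 8595800, CG was 0 of 675 reads, which allows up to 0.444%, 14.7% and 63.1%. At chromosome 2, 12810801 to 12811400, within the stretch from 9 to 16 Mb, it was 18.2%, 25.6% and 74.3%. Without chromosome 2 from 9 to 16 Mb, 1994 tiles were higher and 1720 lower in ros1-3 than in ros1-4. After an estimated share of reads of the other line was removed from each ros1 library, the counts were 8583 and 7155, while against wild type 14491 tiles were higher and 2365 lower in ros1-3, and 12623 and 1956 in ros1-4.

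**Figure D3:**
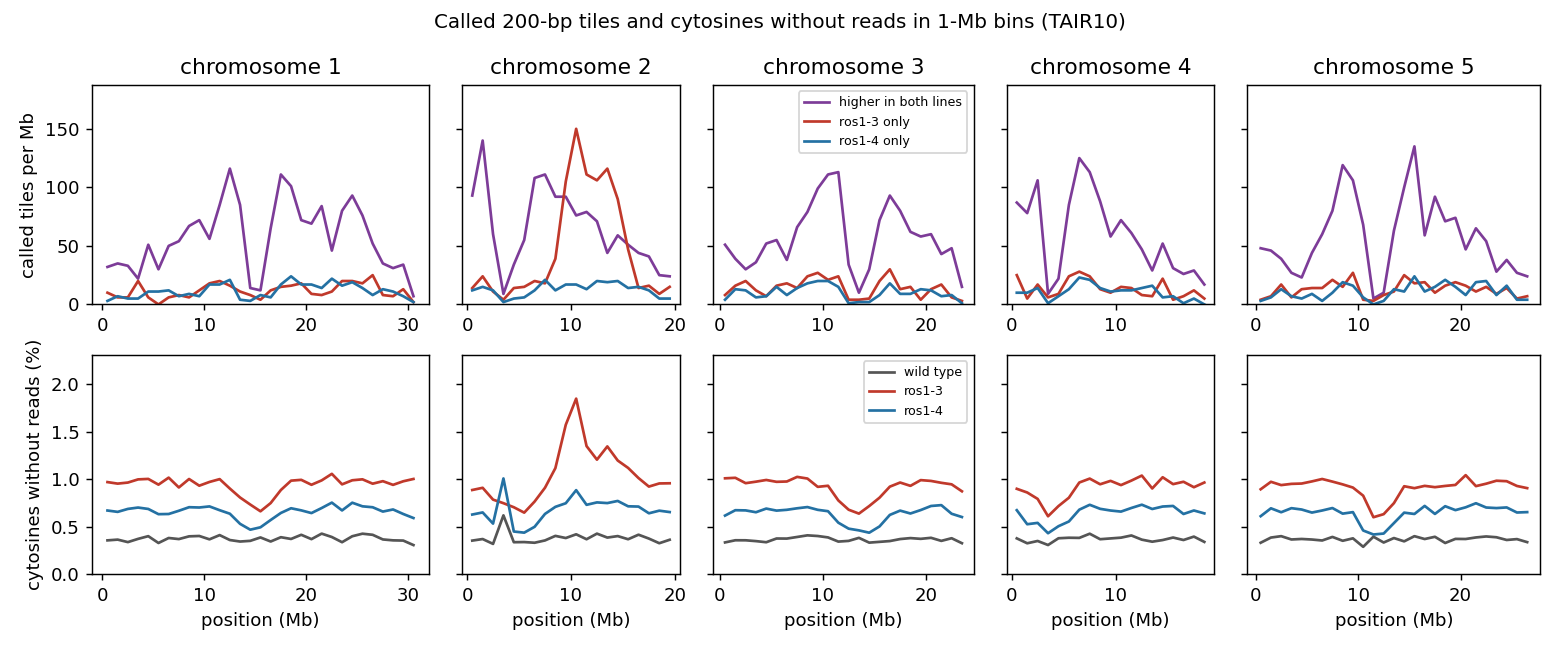
Upper panels show called 200-bp tiles per 1-Mb bin along the 5 chromosomes (TAIR10), for tiles higher in both ros1 lines and tiles called in 1 line alone and differing from the other. Lower panels show, for each library, the percent without reads among cytosines with read neighbours and at least 10 reads in both other libraries. In upper and lower panels ros1-3 rises on chromosome 2 from 9 to 16 Mb, where 32.4% of its single-line tiles lie.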

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

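The tests on cytosines without reads in 1-Mb bins, on the levels in the other line and on the CG and CHG differences with each cytosine counted once were chosen after the results had been seen, as were the bounds set on the planned equal-depth counts and the limits of the chromosome 2 stretch. Direct comparison of the 2 ros1 libraries singled out tiles where the lines differed. Of the tiles higher in ros1-3 and not called in ros1-4, 1923 also differed between the lines by Fisher's exact test, and of the lower tiles 318. The mirror counts for ros1-4 were 1109 higher and 227 lower tiles. At 3 tiles ros1-3 was higher and ros1-4 lower than wild type, and at 5 tiles the reverse. At equal depth at each cytosine, 86.1% of the tiles higher in both lines remained called in both. Most of these calls thus did not need the extra reads of the deeper libraries. Drawing fewer reads keeps each library's level on average and removes calls mainly through lost power, so this test could hardly fail. It does not decide on depth-linked bias in which fragments were read, which stays open.

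The first pattern is the cluster of ros1-3 tiles on chromosome 2 from 9 to 16 Mb, with 725 of 2241 such tiles, for which a candidate explanation is a chromosome segment of another accession in ros1-3, where sequence differences leave cytosines without counts. In ros1-3 each of the 7 bins of 1 Mb in the stretch held a larger share of such cytosines (1.120% to 1.85%) than any of the 114 bins elsewhere (at most 1.118%, in the bin next to the stretch, and otherwise at most 1.06%), while wild type had 0.369% to 0.428% there and up to 0.621% elsewhere. In ros1-4 the share was 0.765% in the stretch and 0.644% elsewhere. These shares count a cytosine only where both other libraries had at least 10 reads. Cytosines missing in both ros1 lines are thus left out, and the shares of both lines understate what they lack. Counted separately among cytosines read in wild type, those without reads in both ros1 libraries made up 0.443% in the stretch and 0.0209% elsewhere. Those without reads in 1 line alone were also more frequent in the stretch, for ros1-3 by more than for ros1-4. A part of the missing cytosines is thus shared by both lines, and a sequence difference shared by both stays open. A planned test on 100-kb bins asked for 5 times the genome median and found 0% of the tiles in such bins, but it was void because that median was already 0.947%. No biological explanation tied to ROS1 was tested for this pattern, and the labels do not give the history of the lines.

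The second pattern is the intermediate level in the other ros1 library where the 2 lines differ, which may come from reads of the 2 libraries being mixed. The cytosines without reads in both ros1 libraries do not decide on mixing, since the filters of the counting are not given. In the same stretch, 322 tiles had at most 2% CG in wild type and at least 60% in ros1-3. There ros1-4 had a median of 12.5% (quartiles 8.52% and 28.1%), with 0.621% of the tiles at or below 2%. But over the 1181 such tiles elsewhere, where the ros1-4 median was 68.1%, the share was also only 1.02%. A partial gain in both lines from the lack of ROS1 is not separated from mixing by these shares and stays open, since a test on 62 tiles with at least 80% CG in wild type and at most 35% in ros1-3, of which 3.23% were at or below 5% in ros1-3, was void because the level read was the one the tiles were chosen by. A stretch absent from part of the ros1-3 DNA cannot be told apart either: the excess of ros1-3 cytosines over elsewhere was 0.749 points below 5% of their neighbours' depth and 0.00777 points at 5 to 35%, which meets the condition set in advance against it, but the test was void because depths of 5 to 35% hardly occur in these files (2.22e-05% of cytosines in wild type outside the stretch, against 0.320% below 5%). The estimated shares were 20.4% of ros1-4 reads in ros1-3 and 13.5% the other way. After their removal 88.0% of the tiles higher in both lines remained called in both. A share of 20.4% or 13.5% moves a CG level by no more points than that, and a CG call needs 40 points. Mixing alone at these shares could therefore not make a CG call, and the test could hardly fail. The 88.0% is thus no evidence on mixing at other shares, and the accuracy of the estimated shares was not tested.

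The third pattern is the higher level over the whole genome in both ros1 libraries. Less complete bisulfite conversion is argued against, since the CHH difference in 5 housekeeping gene bodies was at most 0.425% of the genome difference. Uneven depth over cytosines made up a part of the differences by reads, since the same cytosines counted once each gave smaller ones. Counting each cytosine once left 47.8% of the CG difference in ros1-3 and 45.6% in ros1-4, and 40.9% and 36.4% of the CHG difference. In CHH 66.6% and 58.4% were left, between the bounds set for that test. What was left does not come from weighting by reads. Reads skewed away from AT-rich DNA stay open as the source of the uneven depth. Amplification favouring methylated fragments, which keep more GC after conversion, stays open, since gene-body tiles of intermediate CG level had median differences of 2.31 points in ros1-3 and 2.40 points in ros1-4, with 59.0% and 61.0% of the tiles above wild type. The lack of ROS1 in both lines stays open as well and could not be separated from these with 1 library per genotype.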

How the results depend on the processing

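The values without chromosome 2 from 9 to 16 Mb, with the other line's share removed and with the housekeeping correction, and those of named genes and regions at other minimums of reads, were chosen after seeing the data. Of 110 values of 16 comparison results under alternatives, 66 stayed within 1.5-fold or the counting interval, 44 moved and 0 reversed. Where a value moved, the cause was not tested unless the construction shows it. Tiles of 100 bp, which are more numerous, gave 18079 higher and 3187 lower tiles in ros1-3, 17677 and 3544 in ros1-4, 4444 and 3665 for ros1-3 against ros1-4, and 1544 lower in both lines. Differences of 50, 30 or 20 points gave 6503 and 482, 6483 and 459, 1214 and 749, and 3916 and 185 in both lines. A minimum of 10 reads gave 1737 tiles higher in ros1-3 than in ros1-4 and 402 lower in both lines. With the other line's share removed, which treats rescaled counts as reads, 2365 tiles were lower in ros1-3, and 8583 and 7155 were higher and lower in ros1-3 than in ros1-4. With each cytosine counted once the genome differences of ros1-3 and ros1-4 were 2.001 and 1.98 points in CG, 0.789 and 0.640 in CHG, and 0.401 and 0.317 in CHH. At a minimum of 1 read in the library itself they were 4.71 and 4.68, 2.18 and 1.91, and 0.688 and 0.599. Without chromosome 2 from 9 to 16 Mb they were 1.98 and 1.80 in CHG, 0.620 and 0.554 in CHH, and 4.39 in CG for ros1-4. The housekeeping correction gave 0.604 and 0.540 in CHH. Flanks of 2000 bp were higher in both lines for 426 genes and lower for 3, bodies for 63 and 2, and flanks of 500 bp were lower for 13. Of 115 values of 60 named genes and regions at minimums of 1 or 10 reads, 5 lost the call, 4 moved and 0 reversed. The planned correction with chloroplast reads was not run. No paired analysis was possible because each group holds 1 library, and no library could be left out. Depth limits which sites were tested, since in ros1-3 72.8% of CHH sites and 85.4% of CG sites had at least 4 reads, and tiles of 20 to 25% GC had a mean of 6.39 reads per cytosine.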

Other observations

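The gain at tiles higher in both lines differed between sequences. In CHG, CAG rose from 9.89% in wild type to 38.3% in ros1-3 and 39.5% in ros1-4, and CTG from 10.1% to 37.4% and 38.8%, while CCG rose from 7.14% to 22.5% and 23.4%. In CHH, CTA had the highest levels, from 5.86% to 17.5% and 17.7%, and CAA went from 4.80% to 15.3% and 15.4%. CCT had the lowest, from 2.63% to 6.57% and 6.83%. In CG the level rose from 18.8% to 71.0% and 74.0% at CGT and from 28.0% to 77.9% and 79.8% at CGC. Tiles called lower in ros1-3 alone or ros1-4 alone, and differing directly from the other line, were mostly gene-body tiles called in CG alone, at 80.8% and 57.3%, against 67.0% of the tiles lower in both lines.

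The 2 hypotheses here are about the tiles higher in both lines, and the test on adjacent tiles was chosen after the result had been seen. The first is that gains may lie next to DNA already methylated in wild type. Of the 7139 tiles, 23.5% were below 20% CHG in wild type and beside a tile of at least 20%, against 4.70% of tested tiles and 6.22% in the highest of 1000 circular shifts. The second is that the CHH gain may follow CAA and CTA, the sequences favoured by the methyltransferase CMT2. At these sequences CHH rose 3.11-fold in ros1-3 and 3.14-fold in ros1-4, and at the other CHH sequences 2.61-fold and 2.70-fold. The ratio of the fold gains was at most 1.19. The gain was not particular to these sequences, since CTT rose 2.86-fold and 2.98-fold, near the 2.98-fold and 3.03-fold of CTA, and CCC, with 2.05-fold and 2.10-fold, lowers the pooled value. In the other tested tiles, which include those called higher in 1 line alone, CAA was 1.38-fold and 1.31-fold of wild type by reads. CTT was 1.26-fold and 1.23-fold there, while CAA rose 3.19-fold and 3.22-fold in the tiles higher in both lines. Whether the smaller rise in the other tiles came from uneven depth was not tested.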
